A study of Oryza sativa with 8 samples.

How the data were processed

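The data are gene counts of 8 RNA-seq libraries from rice root tips, made from poly(A) RNA. The deposited table holds whole-number counts per gene and library for 57359 gene IDs, with a length in bases per gene, and the totals differ between libraries. The counts were made with fastp and featureCounts, per the submitters' processing notes, which give no versions. The aligner, the genome build, the annotation's version and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes, or of near-identical copies, cannot be told apart. Amplified reads are not independent molecules, so floors of 3 counts cover counting error only.

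Groups and replicate numbers were taken from the labels. Each column matched 1 library by its name. None of the 57359 gene IDs matched a rice RefSeq gene table of 39387 genes by ID, locus tag or synonym, and the files do not pair the IDs with names. The 30 gene lists fixed beforehand could therefore not be filled, and the list tests and the values of the ethylene signalling genes could not be computed. The rule for named genes asked for an adjusted p under 0.05, a mean of at least 5 CPM in the libraries compared, both libraries of a group above both of the other, a name, and then the highest rises and falls by log2 fold change. The need for a name was dropped once the table was seen to hold IDs only, and the 2 highest rises and 2 deepest falls in ethylene against control were taken and followed in every comparison.

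Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10, which left 27008 genes holding 99.9% of all counts, and 21739 genes had no count in any library. After TMM normalisation, 1 robust quasi-likelihood model with 4 groups was fitted to all 8 libraries, with a common dispersion of 0.093 and 4 residual degrees of freedom. The contrasts were the ethylene effect in the control and calcium groups, the calcium effect without and with ethylene, and their interaction. P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a contrast, with a threshold of 0.05. Standard errors came from the log2 fold change and its F statistic. Log2 CPM used a prior count of 2. The groups, the tests and the other settings, apart from the dropped need for a name and the additions named below, were chosen before the data were examined.

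The fits were tested on simulated counts drawn from the genes' means, dispersions and library sizes, with 50 genes changed at each of 2-, 4-, 8- and 16-fold. For ethylene against control edgeR recovered 12%, 80%, 76% and 88% of these, and for calcium against control 2%, 66%, 90% and 90%. The adjusted threshold depends on how many genes change. These rates therefore do not describe the real ethylene against control, which had 4727 calls. Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, a filter of 1 CPM in 2 libraries, only the 4 libraries compared, the replicate number as a block, a 2-fold minimum and leaving out each library in turn. A filter of a mean of 10 CPM and a comparison of the 4 ethylene libraries with the other 4 were added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.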

Results

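Poly(A) RNA from root tips of rice seedlings of the variety Dongjin was sequenced after growth in the dark with or without ethylene gas and at different calcium chloride supplies. Seeds germinated for 2 days at 37 °C, and seedlings then stayed for 3 days at 28 °C in closed boxes. The 8 libraries fell into 4 groups of 2, labelled control, calcium, ethylene (2 ppm), and calcium and ethylene. The labels give neither the calcium chloride concentrations nor which group stands for low and which for normal calcium, so the groups keep their label names here. Nothing says that the libraries of a group came from separate plants or cultures, so p-values measure only the spread between these libraries, which may be technical. Library totals ran from 19099091 counts in ethylene replicate 3 to 25907083 in ethylene replicate 4. The files do not pair the gene IDs with names, so genes are described by number, size of change and level, and only 4 IDs are named.

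Ethylene separated the libraries. The first principal component of log2 CPM held 55.6% of the variance and placed the 4 libraries without ethylene between -106.6 and -67.1 and the 4 with ethylene between 82.9 and 103.9. Pearson correlations across genes were 0.949 to 0.968 between libraries without ethylene, 0.912 to 0.972 between libraries with ethylene and 0.844 to 0.901 between the kinds. The second component, with 14.7% of the variance, placed ethylene replicate 4 at 110.5 and the others between -55.8 and 18.8. No pair of libraries agreed within read-counting noise, as 1 library listed under 2 names would: chi-square was at least 15.1 per degree of freedom, with reads taken as independent. The lowest value was between control replicate 1 and calcium replicate 1, which share a number but not a group.

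**Figure D1:**
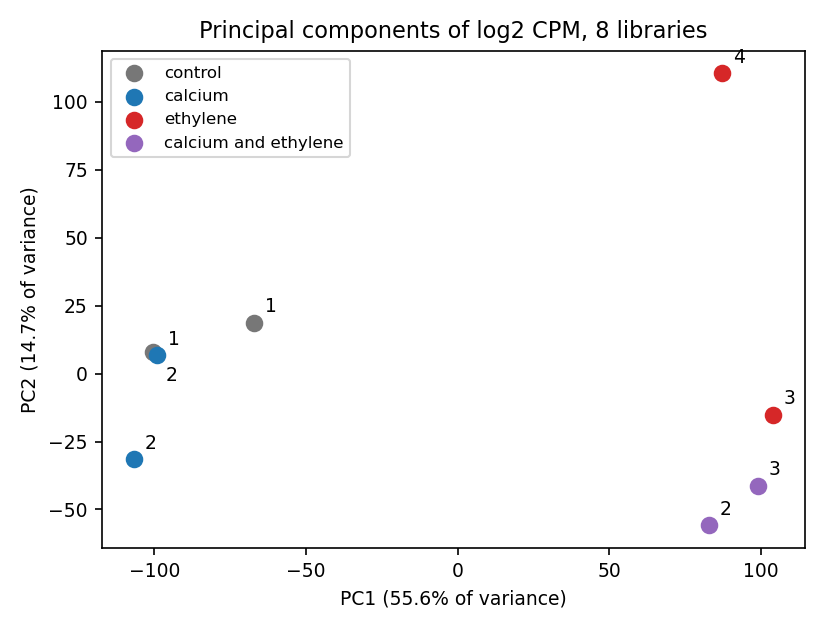
Positions of the 8 libraries on the first and second principal components of log2 CPM, with colours for the 4 groups and numbers for the replicates. The 4 libraries with ethylene sit between 82.9 and 103.9 on the first component, and ethylene replicate 4 sits apart at 110.5 on the second.

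The first comparison asked which transcripts ethylene changed in control roots. Of 27008 genes tested, 2589 rose and 2138 fell, which is 17.5% of those tested. Counting genes at 0 in a group by their lower bound for counting error, 2038 genes rose and 1324 fell by at least 2-fold, and 500 rose and 35 fell by at least 8-fold. Of the called genes, 81 were at 0 in both control libraries and 4 in both ethylene libraries. By mean level in the libraries compared, 58 rose and 10 fell under 1 CPM, 654 and 354 at 1 to 10 CPM, 1529 and 1389 at 10 to 100 CPM and 348 and 385 at 100 CPM or more. A separate fit of genes with a mean of at least 10 CPM called 2115 rising and 2205 falling. The genes that rose held 8.13% ± 0.576 (SD, n = 2) of all counts in control and 20.1% ± 2.68 in ethylene, and the genes that fell held 22.0% ± 1.71 and 9.57% ± 1.84. These genes were picked on those libraries. Genes were called by edgeR's quasi-likelihood test at an adjusted p under 0.05, with a median size of 1.28 on the log2 scale among the called. Calls made up 2.13% of genes under 1 CPM and 35.5% of genes at 100 CPM or more. The count rested on single libraries: it was 283 without control replicate 2, 1985 without ethylene replicate 4 and 2486 without control replicate 1. With only the 4 libraries compared in the fit it was 3044. With the replicate number as a block it was 42. Control and ethylene share no replicate number, so the block compares them only through the other groups. Number 4 occurs only in ethylene replicate 4, so the block fits that library exactly. The ethylene estimate with the block therefore rests on ethylene replicate 3 alone, and the drop in calls is not only an effect of shared numbers. If the numbers mark shared material or handling, its effect was not separated from that of ethylene in this comparison.

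Among genes past the selection rule, AGIS_Os02g031980 and AGIS_Os02g032080 had the highest fitted rises, a rank that depends on the fit's prior count, since both were at 0 in control. AGIS_Os02g031980 had 0 counts in both control libraries and 66.7 ± 17.3 CPM (SD, n = 2) in ethylene, at least 962-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00465). AGIS_Os02g032080 also had 0 counts in control and 45.2 ± 25.8 CPM in ethylene (63.4 in replicate 3 and 27.0 in replicate 4), at least 651-fold higher (adjusted p = 0.00175). Both bounds cover counting error only. Among all genes, 181 were at 0 in 1 control library and at 20 or more counts in the other. AGIS_Os11g013150 fell from 25.3 ± 16.2 to 1.13 ± 1.01 CPM, a log2 fold change of -4.53 (SE 0.87, adjusted p = 0.0169). AGIS_Os10g025450 fell from 116.3 ± 11.4 to 5.97 ± 5.87 CPM, a log2 fold change of -4.31 (SE 0.76, adjusted p = 0.0142). Both falls lost the call without the filter on low counts, with adjusted p = 0.0678 for AGIS_Os11g013150 and 0.0531 for AGIS_Os10g025450, and without control replicate 2, with 0.0893 and 0.0885, and AGIS_Os11g013150 also without ethylene replicate 4 (adjusted p = 0.0868). The log2 fold change of AGIS_Os11g013150 was -3.65 without control replicate 2, -5.91 without ethylene replicate 3 and -3.76 without ethylene replicate 4, and that of AGIS_Os10g025450 was -5.99 without ethylene replicate 3 and -3.51 without ethylene replicate 4. Over 15 alternatives, AGIS_Os11g013150 lost the call under 4 (adjusted p from 1.04e-09 to 0.0893) and AGIS_Os10g025450 under 3 (from 1.43e-05 to 0.0885).

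**Figure D2:**
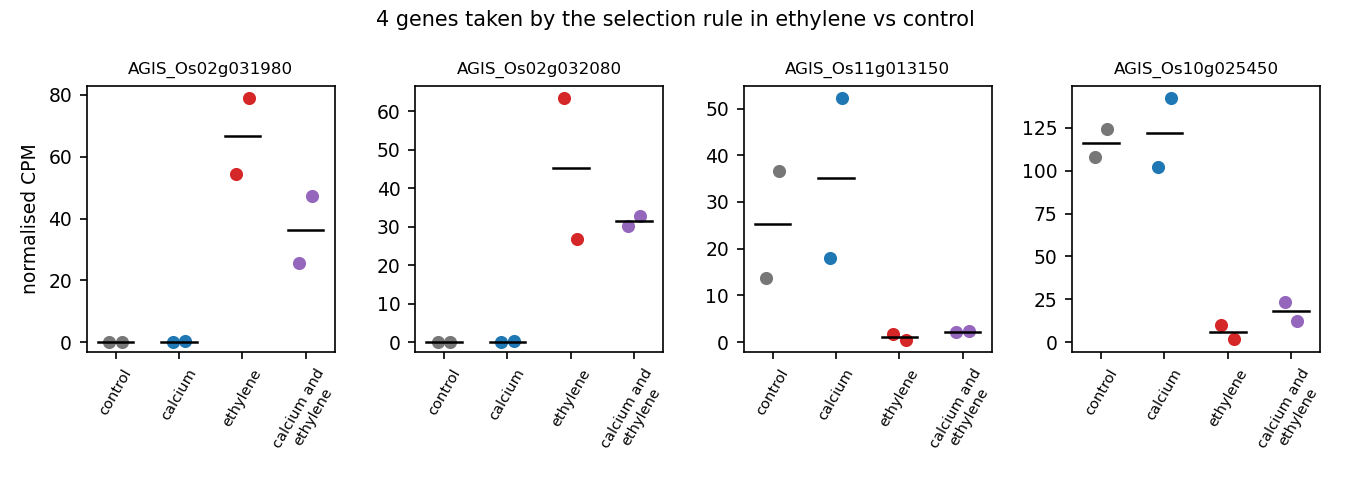
Normalised CPM of 4 genes in each library, by group, with points for libraries and lines for group means. AGIS_Os02g031980 and AGIS_Os02g032080 are at 0 in both control libraries, and AGIS_Os11g013150 and AGIS_Os10g025450 are lower in the libraries with ethylene.

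Libraries with and without ethylene also differed in how many low genes they held. Among genes with a median of about 1 CPM over the other libraries, 2.94% to 8.06% had 0 counts in the libraries without ethylene and 0.0615% to 0.612% in those with ethylene. For each library most of the others had the other ethylene treatment, so low genes that rose with ethylene may widen this gap. Genes seen exactly once numbered 301 to 900 without ethylene and 1202 to 1525 with it. Ethylene replicate 4 was at least 8-fold lower than each of the other 3 ethylene libraries in 106 genes of at least 5 CPM, against 2, 4 and 1 genes for the others. Those 106 genes held 0.0518% of its counts and 1.70%, 1.98% and 3.01% of the others', against 0.0823% to 0.115% in the libraries without ethylene, and 67 of them were also at least 8-fold lower in all 4 of those. Of the 106, 5 were called in ethylene against control. The 106 were picked for a gap between ethylene libraries, which enters each gene's spread in the fit, so few calls follow from the picking.

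The next comparison asked the same of ethylene in roots of the calcium groups. In calcium and ethylene against calcium, 2540 genes rose and 2258 fell, or 17.8% of those tested. With genes at 0 counted by their lower bound for counting error, 1989 rose and 1402 fell by at least 2-fold, and 540 rose and 27 fell by at least 8-fold. Of the called genes, 154 were at 0 in both calcium libraries and 2 in both calcium and ethylene libraries. By level, 134 rose and 2 fell under 1 CPM, 756 and 518 at 1 to 10 CPM, 1382 and 1354 at 10 to 100 CPM and 268 and 384 at 100 CPM or more. AGIS_Os02g031980 rose from 0.184 ± 0.260 to 36.5 ± 15.1 CPM (adjusted p = 0.00622). All 9 of its calcium counts were in calcium replicate 2, so the log2 fold change of 7.50 (SE 0.80) rested on that library: it was 6.60 without calcium replicate 1, and without replicate 2 the group was at 0. AGIS_Os02g032080 rose from 0.173 ± 0.0441 to 31.5 ± 1.85 CPM, 181.7-fold (SE 0.58 on the log2 scale, adjusted p = 0.00283). AGIS_Os11g013150 fell from 35.2 ± 24.1 to 2.27 ± 0.253 CPM (adjusted p = 0.0225) and AGIS_Os10g025450 from 122 ± 28.4 to 18.0 ± 7.61 CPM (adjusted p = 0.0401). The call of AGIS_Os11g013150 was lost under 4 of 15 alternatives, with adjusted p = 0.105 without calcium replicate 2 (log2 fold change -2.97 in place of -3.95), 0.109 and 0.113 without calcium and ethylene replicates 2 and 3 and 0.0818 without the filter on low counts. That of AGIS_Os10g025450 was lost under 7, with adjusted p = 0.0746 and 0.0758 without control replicates 1 and 2, 0.103 and 0.193 without calcium replicates 1 and 2, 0.102 and 0.182 without calcium and ethylene replicates 2 and 3, and 0.13 without the filter. The count of called genes was 535 without calcium and ethylene replicate 3, 839 without calcium replicate 2, 1110 without calcium and ethylene replicate 2 and 3089 without calcium replicate 1. Of the 106 genes low in ethylene replicate 4, 14 were called here. Their gap between ethylene libraries enters the spread in the shared fit, so few calls do not show that they were unchanged. In all libraries without ethylene, 67 of them were at least 8-fold lower than in the other ethylene libraries.

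The ethylene changes at the different calcium supplies were compared over disjoint libraries. Of the genes called in either comparison, 3161 were called in both, 1669 rising in both, 1492 falling in both and 0 in opposite directions. Independent lists of those sizes would share 243 rising and 179 falling genes. That takes every gene as equally likely to be called. Calls were more frequent at higher levels and both comparisons came from 1 fit, so these expected numbers may be too low. Genes called in ethylene against control had a median signed log2 change of 1.28 there and of 1.11 in calcium and ethylene against calcium, where 99.6% kept their sign. In reverse, genes called in calcium and ethylene against calcium had 1.31 there and 1.11 in ethylene against control, where 99.4% kept their sign. Each median was lower in the comparison that had not picked the genes, so the drop does not show a smaller ethylene effect with calcium. Across all tested genes, which are not independent replicates, the fold changes had a Pearson correlation of 0.759 and a Spearman correlation of 0.787. The median of 1.11 in calcium and ethylene against calcium was 2.31 without control replicate 2, where far fewer genes were called.

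**Figure D3:**
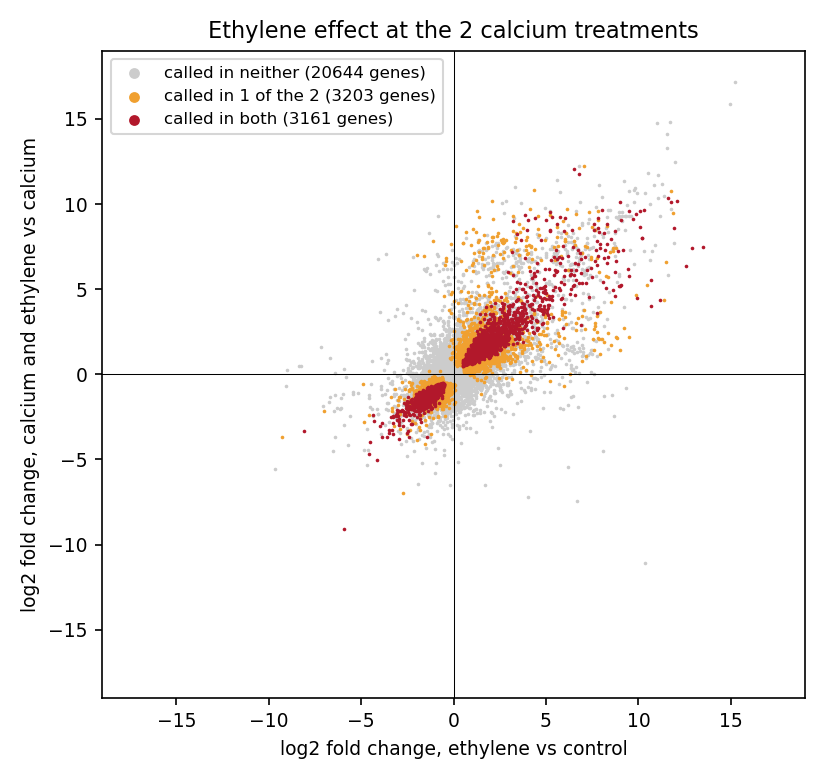
Fitted log2 fold change of each of 27008 genes in ethylene against control (x axis) and in calcium and ethylene against calcium (y axis), coloured by where it was called. The 3161 genes called in both lie at the lower left and upper right, with the same sign on both axes, and folds of genes at 0 in a group depend on the fit's prior count.

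Calcium against control asked what the calcium supply changed without ethylene. No gene was called by edgeR at an adjusted p under 0.05, and the lowest adjusted p was 1. An unadjusted p under 0.05 was reached by 1037 genes, where 1350 would be reached by chance. A number below chance means that these p-values did not follow chance, and it is not evidence of no effect. Recovery in simulated data may therefore not hold for these libraries. Of 13865 genes at 10 CPM or more, 82.7% had a 95% interval of the fold change within 2-fold in either direction. AGIS_Os11g013150 had 35.2 CPM in calcium and 25.3 in control, and AGIS_Os10g025450 122 and 116.3 (adjusted p = 1 for both). AGIS_Os02g031980 and AGIS_Os02g032080 had 9 and 8 counts in calcium and 0 in control, with adjusted p = 1. In simulated data for this comparison edgeR recovered 2% of 2-fold and 66% of 4-fold changes. DESeq2 called 6 genes and edgeR without the filter on low counts 15, and DESeq2's calls on the simulated data were 29.7% false, against 12.7% for edgeR.

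Calcium and ethylene against ethylene asked the same in the presence of ethylene. No gene was called by edgeR, with a lowest adjusted p of 0.281, and 2076 genes had an unadjusted p under 0.05 against 1350 by chance. Of 14272 genes at 10 CPM or more, 71.8% had a 95% interval within 2-fold. AGIS_Os02g031980 had 36.5 CPM against 66.7 in ethylene (adjusted p = 0.677) and AGIS_Os02g032080 31.5 against 45.2 (adjusted p = 0.709). AGIS_Os11g013150 had 2.27 against 1.13 CPM (adjusted p = 0.739) and AGIS_Os10g025450 18.0 against 5.97 (adjusted p = 0.644). The count of called genes was 180 by DESeq2 and 116 without the filter on low counts. It also rose above 0 without ethylene replicate 3. That fit left ethylene replicate 4 alone in its group, the library at 110.5 on the second principal component. On data simulated for this comparison, 15.9% of edgeR's calls and 31.8% of DESeq2's were false.

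The changes with calcium had a Spearman correlation of 0.298 between roots without and with ethylene across all tested genes, with 63.8% of genes of the same sign and a Pearson correlation of 0.128. The Spearman correlation was 0.133 without calcium replicate 2, 0.168 without control replicate 1 and 0.524 in a separate fit of genes of at least 10 CPM. As no gene was called in calcium against control, the planned median over such genes could not be computed.

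The interaction asked whether ethylene's effect differed between the calcium supplies. No gene was called by edgeR, the lowest adjusted p was 1, and 644 genes had an unadjusted p under 0.05 against 1350 by chance. As in calcium against control, a number below chance is not evidence of no effect, and simulated recovery may not hold here. Each of the 4 named genes had an adjusted p = 1. Of 14293 genes at 10 CPM or more, 57.5% had a 95% interval of the difference within 2-fold. On simulated data edgeR recovered 0%, 44%, 64% and 80% of 2-, 4-, 8- and 16-fold differences, and DESeq2 6%, 60%, 78% and 86%. Of the calls on these data, 11.3% of edgeR's and 27.7% of DESeq2's were false. DESeq2 and edgeR without the filter on low counts each called 1 gene. Genes were also called without ethylene replicate 3, which left ethylene replicate 4 alone in its group, and without calcium replicate 1.

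**Figure D4:**
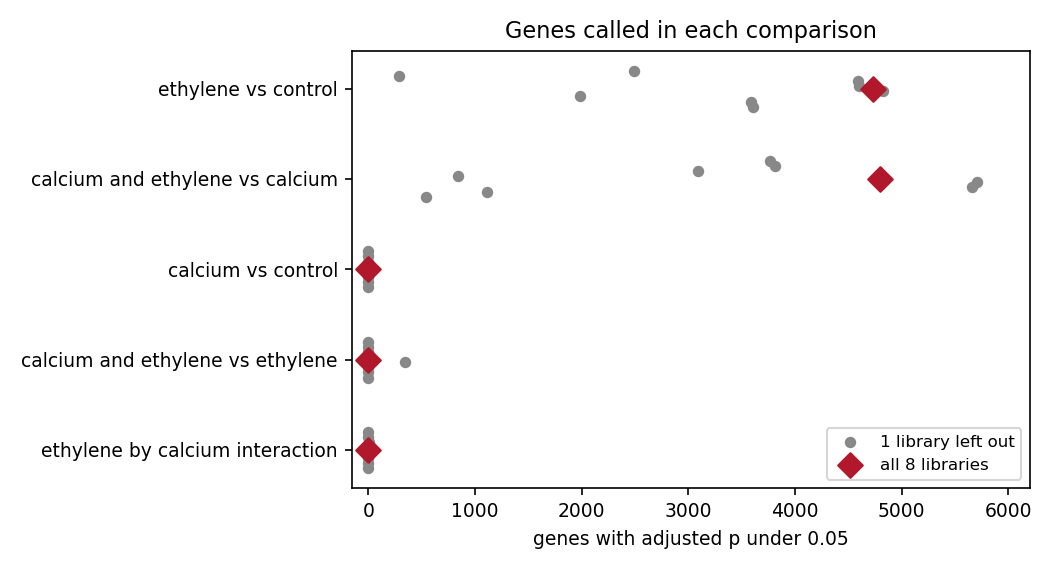
Number of genes with an adjusted p under 0.05 in each of 5 comparisons, for all 8 libraries (diamonds) and with each library left out in turn (points). Ethylene against control has 4727 genes with all libraries and 283 to 4820 with 1 left out, and calcium against control has 0 throughout.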

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

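The filter of a mean of 10 CPM and the pooled comparison of ethylene with air were chosen after the data had been seen. In ethylene against control, the 4727 calls became 3044 with only the 4 libraries compared and 42 with the replicate number as a block, and 283 to 4820 with 1 library left out (283 without control replicate 2, 1985 without ethylene replicate 4, 2486 without control replicate 1). In calcium and ethylene against calcium, the 4798 calls became 3536 with the block and 535 to 5707 with 1 library left out (535 and 1110 without calcium and ethylene replicates 3 and 2, 839 and 3089 without calcium replicates 2 and 1). With 1 library left in a group, that library is assumed to vary like the other groups. DESeq2 called 6 genes in calcium against control, 180 in calcium and ethylene against ethylene and 1 in the interaction, and no filter on low counts gave 15, 116 and 1. Leaving out 1 library gave 0 to 0, 0 to 345 and 0 to 20 calls, with 345 and 20 without ethylene replicate 3 and 1 interaction call without calcium replicate 1. The median signed change of 1.11 in calcium and ethylene against calcium was 4.95 with the block, 0.928 in a fit of genes of at least 10 CPM and 1.02 to 2.31 with 1 library left out. The Spearman correlation of the calcium changes, 0.298, was 0.339 with the 1 CPM filter, 0.156 with the block, 0.524 in a fit of genes of at least 10 CPM and 0.133 to 0.272 with 1 library left out. Fewer genes and fewer libraries enter some of these fits, and otherwise the cause was not tested. Among the genes called in each ethylene comparison, 0 changed sign under the alternatives other than the block, where 3 did in ethylene against control. For the 4 named genes in both ethylene comparisons, each under 15 alternatives, 18 values lost the call, 0 reversed and the others kept it. Under the block the falls in ethylene against control had adjusted p = 0.0567 for AGIS_Os11g013150 (log2 fold change -4.57) and 0.0585 for AGIS_Os10g025450 (-2.80). The replicate numbers were not treated as pairing the libraries, since no label says what they mean and not every correlation was over 0.1: deviations of same-numbered libraries correlated at 0.180 between control and calcium, 0.104 and 0.107 between those and calcium and ethylene, and 0.0154 between ethylene and calcium and ethylene. The block left 1 residual degree of freedom in place of 4. It raised the median SE of ethylene against control from 0.327 to 0.523 and that of calcium and ethylene against calcium from 0.328 to 0.357. Only ethylene replicate 4 has the number 4, so with the block the ethylene group rests on ethylene replicate 3 alone. The gene list tests and the values of the ethylene signalling genes were not run, since no ID matched the gene table used and the files pair none with a name.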

Other observations

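Every test in this part except that of neighbouring ID numbers was chosen after the result had been seen, and thresholds on fold, level and count were set after several exploratory passes over the counts, so values at other thresholds are given where they were computed.

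Ethylene libraries against the other 4, pooled over calcium, gave 5370 higher and 4916 lower genes. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as its 10286. The highest of the others, which mix libraries with and without ethylene, gave 0. Chance assignment is argued against but not excluded, since 1 of 35 is the smallest share that these splits can give. The split was tested after the libraries had been seen to separate by ethylene. Technical differences that follow ethylene are not excluded by this.

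A block of genes was low in ethylene replicate 4 and held 0.0518% of its counts, near the 0.0823% to 0.115% of the libraries without ethylene: 106 genes at 8-fold and 5 CPM and 23 to 429 over the other thresholds tried, where no other ethylene library exceeded 41. A library from air is argued against, since in genes called in calcium and ethylene against calcium its median change from control was 1.13 times that of replicate 3, and low depth by a total 1.36 times the lowest of the others. One source of RNA in varying amount cannot be told apart: log2 ratios of the genes between the other ethylene libraries spread 1.75 times as widely as those of level-matched genes, but 1.18 times (0.979 to 1.26 over the pairs) as widely as those of 73 other genes at least 8-fold higher with ethylene, and their medians were -0.410 and -0.425 over calcium and ethylene replicate 3. Several sources, or a difference in tissue sampled, may also account for the block. No biological explanation was tested.

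Libraries without ethylene held more zero counts. Depth is argued against, since at equal totals the lowest ethylene library still detected 1388 more genes than the highest without. Genes wholly absent without ethylene are argued against as the whole cause. Among genes at 10 or more counts in all 4 ethylene libraries, 34.7% of 957 zeros without ethylene were also 0 in the other library of the group. Of such genes, 30 were 0 in all 4 libraries without ethylene. A partner with any count was taken as against absence, so genes strongly lowered but not absent without ethylene cannot be told apart by this test. Fewer distinct molecules in those libraries cannot be told apart: genes at 0 in 1 library and at 10 or more in its partner were 3.36 times as many without ethylene, but 2.62, 2.28 and 1.05 times at minimums of 5, 20 and 50, and the groups without ethylene averaged 3.13, 5.2, 4.97 and 3.85 times calcium and ethylene but 2.26, 2.49, 1.48 and 0.611 times ethylene at minimums of 5, 10, 20 and 50. The difference follows ethylene and may contribute to calls of low genes, although 2918 of the genes called in ethylene against control lay at 10 to 100 CPM and 733 at 100 CPM or more.

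Both calcium groups lay lower on the ethylene axis than their partners. Over 2615 genes that differed at least 2-fold by ethylene and reached 10 CPM, scores were -0.482 and -0.674 in control, -0.685 and -0.958 in calcium, 0.688 and 1.07 in ethylene and 0.454 and 0.628 in calcium and ethylene, so calcium differed by -0.243 without ethylene and by -0.337 with it, a sum of -0.580. Chance assignment of calcium cannot be told apart with 36 assignments: the exact two-sided permutation p of 0.0556 is the smallest they can give, the highest other difference was 0.570, and at 4 of the 9 threshold pairs tried p was above it, up to 0.167. Ethylene replicate 4 alone cannot be told apart as the cause of the difference with ethylene, of which 0.31 stayed without it (-0.104, a sum of -0.339, and -0.511 without ethylene replicate 3), and the difference without ethylene was -0.147, -0.389 and -0.120 without control replicate 1, calcium replicate 1 and calcium replicate 2. Fewer molecules in the calcium libraries stay open too, since genes seen once were apart in 0 of the 2 ethylene levels, with means of 410.5 in calcium against 600.5 in control and 1341 in calcium and ethylene against 1363.5 in ethylene, and an effect of the calcium supply was not tested apart from these.

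The calcium changes without and with ethylene correlated at 0.528 over genes of at least 10 CPM, against at most 0.403 in size for the other 8 relabellings. This was taken from differences of mean log2 CPM and not from a fit of those genes (0.524). Over all genes the correlation was 0.307 (0.298 in the fit, 0.133 without calcium replicate 2), against 0.197. Chance assignment of calcium cannot be told apart, since 1 of 9 relabellings is the smallest share possible. The same libraries gave the ethylene axis scores, so the 2 results are not independent.

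Genes whose next ID number was also called in the same direction made up 13.6% of the 3095 genes called in ethylene against control whose next ID was tested, above the highest of 1000 random placements, 10.4%, and 12.2% of 3198 such genes in calcium and ethylene against calcium. A candidate explanation is that neighbouring genes change together, but the order of IDs along chromosomes is assumed, and shared reads and levels were not controlled.

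Control, calcium, and calcium and ethylene replicates 2 shared 18 genes at 10 or more counts that were at 0 in the other library of each group, against at most 1 for the other 7 ways to take 1 library from each. Shared plant material or handling of libraries numbered 2 is a candidate explanation. Control and ethylene share no replicate number, so such a difference was not separated from ethylene in ethylene against control.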
